A study of Mus musculus with 2 samples.

How the data were processed

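Total RNA was extracted, per the labels' protocols, from dissected ureters of NMRI mouse embryos, amplified into cRNA with aminoallyl nucleotides and coupled to AlexaFluor555 or AlexaFluor647. Per the labels, 2 arrays were hybridised, each with Rbpj-cKO and control RNA of the same sex, and the dyes were swapped between them. The labels do not say how many embryos gave each RNA, or whether RNA was pooled, so p-values rest on these 2 arrays and not on a spread between embryos. The spread they use is mostly pooled over all features, since eBayes added 10.3 prior degrees of freedom to 1 residual degree of freedom. Both arrays lie on the same slide and in the same scan, so neither was tested as a batch.

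The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1, as named in the submitters' processing notes. Per the file headers, the mean and background signals are an intensity with no normalization, and the processed signals are an intensity after background subtraction, detrending and linear and lowess dye normalization. Per the file headers, the log ratio is the log10 of red over green processed signals. The deposited series value table holds a score per probe, and its making is not given in the sources used here. Set against the scanner files, it is a signed fold of Rbpj-cKO over control from the processed signals, with signals below 15.79 (male array) and 13.77 (female array) raised to that floor. With this floor 100% of the 39030 probes of 1 spot matched on each array within 0.001 on the log2 scale, and no value lay between -1 and 1. The median of each column was 1.0, so no further centring was needed. The 399 probes with 10 spots were summarised there in a way that stays unknown. Every per-sample column of the table was used.

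From the scanner files, mean signals were corrected with limma's normexp against the median background (offset 50) on all spots. Loess was then fitted within each array with control spots at weight 0. Control spots and spots marked as outliers (200 on the male and 274 on the female array) were left out, and spots of a probe were averaged. Probes were kept where they were well above background on both arrays in the Rbpj-cKO channel or on both in the control channel. Of 39429 probes, 26412 were named through their RefSeq accession in the GRCm38.p6 gene table and 13017 kept the name in the files. A gene was represented by its probe of highest mean log2 intensity over the 4 channels, which left 20989 features. Probe positions are those in the files, on mm9, and the exon or intron a probe lies in was not analysed here.

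Each ratio was turned to Rbpj-cKO over control, so that a dye effect cancels in the mean of the arrays and enters the residual. Features were tested with lmFit and eBayes (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The fit has 1 residual degree of freedom, and eBayes added 10.3 prior degrees of freedom. Where a gene was not well above background in a group, a bound was computed from the lowest signal well above background on each array, after loess and Aquantile. In 2-colour data such a bound is open to dye bias, which the swap balances here. It takes no account of the error of the ratio. Features changed at least 1.5-fold on both arrays were counted without a test.

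Before the data were examined, 28 gene lists were fixed. The 27 with at least 5 measured genes, other than the sex-linked genes, were tested with camera (preset correlation 0.01), and with an estimated correlation and fry as alternatives. The sex-linked list (3 measured genes) had a median of 0.09 and no member past the test. Genes named in the text follow a rule fixed at the same time. It takes Rbpj, Tbx18, 7 Notch genes and 5 smooth muscle genes whatever their values. It adds the 12 highest and the 12 lowest among features past the test with at least 1.5-fold change on both arrays, filled up by features with such a change ranked by the smaller of their 2 ratios. It also takes up to 4 members per list, past the test first, then the highest and lowest. Features without a gene symbol are counted and not named, and exceptions are marked as chosen after their values were seen.

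The limma step was tested on simulated data for the 20989 features of this comparison, with the observed dye part of each feature kept. Of 50 features changed 3-fold and 50 changed 4-fold, 100% were recovered, of 50 changed 2-fold and of 50 changed 1.5-fold, 0% were, and no unchanged feature was called. The changed features were given exact ratios, with no error in their mean, and the unchanged ones a normal spread. These shares are thus not the power or the rate of false calls in the real data. The camera step, on 27 simulated lists of the real sizes, recovered 9 of 9 lists shifted by 0.2 with 0 false calls under the preset correlation. It recovered 0 of 9 with an estimated correlation, so a lack of calls in that setting does not decide against a list. The simulated genes were drawn independently, whereas the estimated correlation of the mesothelial list was 0.394. The 0 false calls thus do not carry over to lists of correlated genes. Alternatives covered the background correction, the normalization within and between arrays, Agilent's processed signals, the series value table, the filter on dim probes, the choice of probe, the eBayes options, the fold threshold, the list test and each array left out.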

Results

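Ureters of mouse embryos at E18.5 were compared between Rbpj-cKO embryos and controls by 2-colour microarray. The ureter at this stage is a tube of urothelium wrapped in mesenchyme that has formed smooth muscle. Rbpj encodes the DNA-binding protein through which Notch receptors act on their target genes. In the Rbpj-cKO embryos a cre recombinase expressed from the Tbx18 locus, which is active in the mesenchyme around the ureteric bud, acts on 2 floxed Rbpj alleles. The control embryos carry at least 1 floxed Rbpj allele, and their labels list no cre. The comparison asks which transcripts differ in the late fetal ureter when Rbpj is targeted for deletion in its mesenchyme. There were 2 arrays, each with Rbpj-cKO RNA in 1 channel and control RNA of the same sex in the other. The male array carried the Rbpj-cKO RNA in the red channel (AlexaFluor647) and the female array carried it in the green channel (AlexaFluor555). The median signal was 13.3 times the median background in green and 6.78 times in red on the male array, and 11.2 and 6.38 times on the female array. Between 66.8% and 71.1% of the probe spots were well above background in each of the 4 channels, and no probe spot was saturated. The number of arrays limits the precision. Ratios below are log2 of Rbpj-cKO over control, and a mean is over the 2 arrays. A pair of ratios in parentheses is the male and then the female array, given where a mean rests mostly on 1 array.

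Rbpj itself had a log2 ratio of -1.58 on the male and -0.93 on the female array at its brighter probe (mean -1.25, SD 0.46, n = 2), a 2.39-fold lower level in Rbpj-cKO ureters, with a limma adjusted p of 0.0761. The value missed the threshold of 0.05. The probe lies on chromosome 5 at 54048503 to 54048562 (mm9). A second, dimmer Rbpj probe at 54044777 to 54044836 gave -0.42 and -1.12. Tbx18, of which 1 allele carries the cre in Rbpj-cKO embryos, had -0.11 on the male and 0.47 on the female array (mean 0.18, adjusted p = 1). Whether either Rbpj probe lies in the part that cre removes is not given in the sources used here, so these values do not check the labels. When only probes well above background in both channels of both arrays were tested, the adjusted p of Rbpj was 0.0456. It was 0.0126 with an intensity trend in the prior variance, a setting applied to Rbpj after the results were seen, and 0.0575 or more under the 9 other settings that gave a p.

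Muscle transcripts and a Notch target were among the transcripts that fell in Rbpj-cKO ureters. Myh6, the alpha cardiac myosin heavy chain, fell 5.14-fold (log2 ratio -2.36, SD 0.07, n = 2; limma adjusted p = 0.000758). Pcp4, a small calmodulin-binding peptide, fell 3.30-fold (-1.72, SD 0.04; adjusted p = 0.00479). Ckm, the muscle creatine kinase, fell 2.69-fold (-1.42; adjusted p = 0.0203), and Myl4, the embryonic and atrial myosin light chain, fell 2.65-fold (-1.40, SD 0.45; adjusted p = 0.0356). Heyl, a basic helix-loop-helix repressor that Notch signalling induces, fell 2.60-fold, with -1.57 on the male and -1.19 on the female array (adjusted p = 0.0247). Of 20989 features tested, 26 passed, 18 of them lower and 8 higher in Rbpj-cKO ureters.

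A further 7 of the lower transcripts are described by gene. The C-type lectin Colec11 fell 3.97-fold (log2 ratio -1.99), Wfdc18, with a whey acidic protein domain, fell 3.83-fold (-1.94), and the eosinophil chemokine Ccl11 fell 2.95-fold (-1.56). The melanocortin receptor Mc4r had a log2 ratio of -1.48, the muscle-expressed deaminase relative Apobec2 of -1.45, the Ras-like GTPase Rergl of -1.44, and the joint lubricant proteoglycan Prg4 of -1.37. The limma adjusted p of these 7 genes lay between 0.00404 and 0.0247. Another 5 named transcripts that passed, listed after their values were seen because they are so few, were Olfr558 (-1.34, well above background in the Rbpj-cKO channel on 1 of 2 arrays), Myo18b (-1.26), Pcp4l1 (-1.26), P2ry14 (-1.23) and Angptl1 (-1.22). A further lower feature bears no gene symbol. Probes of 1 gene did not always match: a second Prg4 probe, well above background on 1 array in each channel, had a mean of -0.02, and of the 2 other Myo18b probes above background 1 had -0.75 and 1 had 0.06.

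Among the transcripts that rose was Gdnf, the ligand that signals through the receptor Ret, which rose 2.57-fold (log2 ratio 1.36, SD 0.04, n = 2; limma adjusted p = 0.0211). The cytochrome P450 Cyp2e1 rose 2.60-fold (1.38) and its second probe gave 1.54, and the neural adhesion molecule Cntn6 rose 2.70-fold (1.43), both with an adjusted p of 0.0211. The G protein-coupled receptor Mrgprx2 was not well above background in the control channel of either array, and its log2 ratio was 1.80 (limma adjusted p = 0.00479). With the control raised to the lowest signal well above background, Mrgprx2 was 3.47-fold higher in Rbpj-cKO ureters. That fold takes no account of the error of the ratio. Btbd9, a protein with a BTB domain, rose 3.73-fold at 1 probe (1.28 on the male and 2.52 on the female array; adjusted p = 0.0211), while its 2 other probes gave means of 0.05 and 0.16. The other 3 higher features bear no gene symbol. Among them was the largest change of all features past the test (log2 ratio 2.90, 7.47-fold higher, limma adjusted p = 0.000699). The others had 2.01 and 1.56, the latter not well above background in the control channel of either array. Genes that missed the threshold but were at least 1.5-fold higher on both arrays included Crhbp (mean 1.97, but 0.84 and 3.11 on the male and female array), the oestrogen receptor Esr1 (1.34, adjusted p = 0.0718), the nephron progenitor factor Six2 (1.17), Cadps (1.08), Cntn4 (1.05), a relative of Cntn6, and Kif26b (0.92). Six2 had a second probe at 0.38, and Esr1 had a dimmer probe at 0.29. The counts of genes depended on the processing, and no feature passed with median centring in place of loess, with Agilent's processed signals, with the series value table or without a filter on dim probes (lowest adjusted p 0.158, 0.0536, 0.0754 and 0.0531). With the mean of a gene's probes 10 features passed, and with an intensity trend in the prior variance 41 passed.

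Changes of at least 1.5-fold in the same direction on both arrays were found for 134 features, 43 higher and 91 lower in Rbpj-cKO ureters. Independent arrays would give 36.3. The lower ones included Heyl, Myh6, Pcp4, Ckm and Rbpj, and the higher ones included Hey1, Gdnf, Esr1 and Six2. As many as 218 features changed at least 1.5-fold in opposite directions, where independent arrays would give 36.1. No test was made of these counts, and with Agilent's processed signals they were 290 and 412. With median centring in place of loess they were 122 and 1001.

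**Figure D1:**
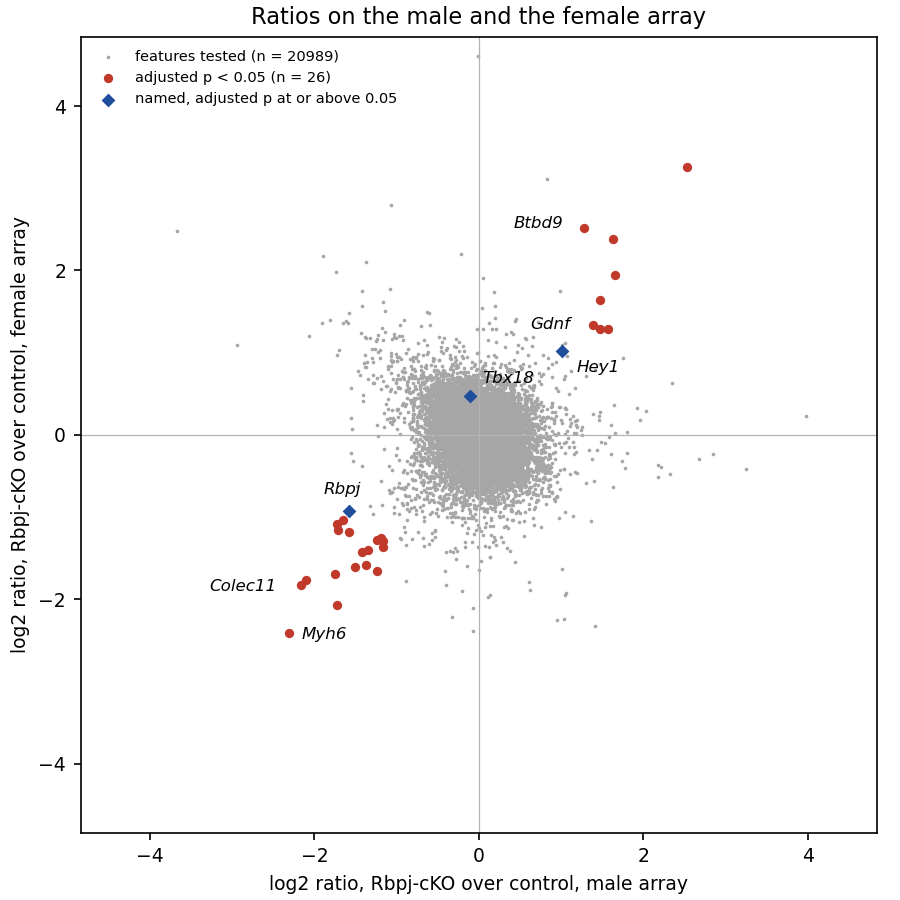
Log2 ratio of Rbpj-cKO over control on the male array (x axis) against the female array (y axis) for each of the 20989 features tested; red points are the 26 features past the limma test and blue diamonds are Rbpj, Hey1 and Tbx18, which missed it. The red points lie in the lower left and upper right corners, and the cloud of other features leans the other way, with a correlation across features of -0.18.

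Smooth muscle contractile genes were lower in Rbpj-cKO ureters as a group by camera with the preset correlation, by a small amount per gene, and not by fry or with an estimated correlation (adjusted p = 0.792 with an estimated correlation). The 46 contractile and cytoskeletal genes had a median log2 ratio of -0.19, with -0.21 on each array. Over all genes tested, Pcp4 and Ckm fell and the other 44 did not pass; adjusted over the list alone, 8 fell, namely Aoc3, Ckm, Des, Ldb3, Pcp4, Synm, Synpo2 and Tnnt2. The intermediate filament gene Des had -0.64, and the highest members, the focal adhesion gene Tln1 and the actin-bundling gene Palld, had 0.24 and 0.18. The core markers of differentiated smooth muscle had Myh11 -0.35, Cnn1 -0.38, Acta2 -0.20 and Tagln -0.13, each with a limma adjusted p of 1, and Myocd, the coactivator that drives them, had -0.29. The camera adjusted p of the list was 2.23e-14 with the preset correlation and 0.792 with an estimated correlation. The latter setting recovered 0 of 9 shifted lists in the simulation, so here and below its result does not decide. Fry for change in 1 direction, which the simulation did not cover, called 0 of the 27 lists (lowest fry adjusted p 0.533). This holds for each list below.

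Skeletal and cardiac muscle markers were lower by camera with the preset correlation (adjusted p = 1.26e-12), and not with an estimated one (adjusted p = 0.792 with an estimated correlation). The 21 measured genes had a median of -0.33, Myh6, Ckm and Myl4 fell, and 18 did not pass. Adjusted over the list alone 7 fell, which adds Actc1, Casq1, Tnnc1 and Tnnc2, and only Ckm is also in the contractile list. The fast myosin light chain Myl1 had 0.37 (0.01 and 0.74). Genes of smooth muscle excitation and calcium handling (35 genes) had a median of -0.13; none passed over all genes, and adjusted over the list alone Kcnj8, Ptger3, Rgs2 and Ryr3 fell. The prostaglandin receptor Ptger3 had -0.88, the ryanodine receptor Ryr3 -0.71 and the potassium channel Kcnj8 -0.68, while the channels Hcn3 and Cacna1h had 0.26 and 0.24. This list had a camera adjusted p of 2.54e-05, and 0.792 with an estimated correlation. The 31 regulators of smooth muscle transcription had a median of 0.02 and none passed (camera adjusted p = 0.300), with Sox9 at -0.47, Klf4 at -0.38, Smad6 at 0.29 and Klf5 at 0.33 (-0.01 and 0.67).

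**Figure D2:**
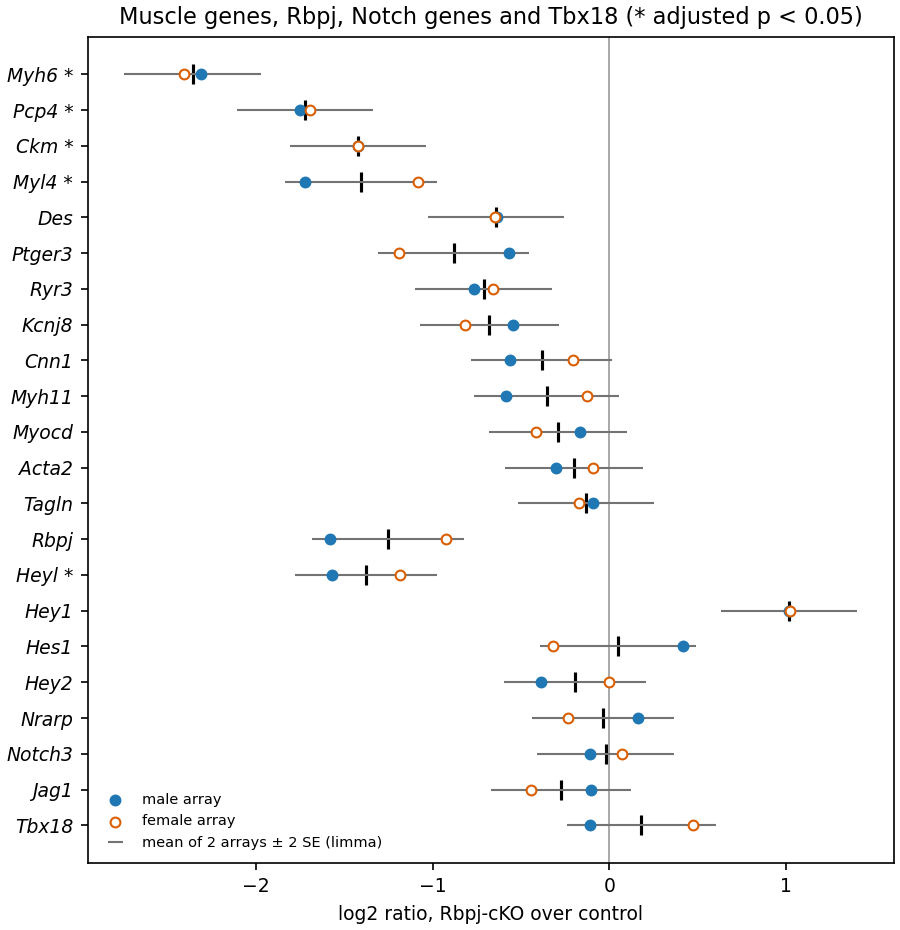
Log2 ratio of Rbpj-cKO over control (x axis) for muscle genes, Rbpj, Notch genes and Tbx18; filled circles are the male array, open circles the female array, ticks their mean and bars 2 SE from limma on each side, and stars mark genes past the limma test. Myh6, Pcp4, Ckm, Myl4 and Heyl lie below -1.0 on both arrays, and the core smooth muscle markers Cnn1, Myh11, Myocd, Acta2 and Tagln have means between -0.38 and -0.13.

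Notch target genes did not move as a group. Of 24 measured, Heyl fell and 23 did not pass over all genes, and adjusted over the list alone Heyl fell and its relative Hey1 rose. Hey1 had a log2 ratio of 1.02 on both arrays (2.03-fold higher, limma adjusted p = 0.122). The classical target Hes1 had 0.42 on the male and -0.32 on the female array, Hey2 had a mean of -0.19, Nrarp of -0.03 and Notch3 of -0.02, and the means of Nrarp and Notch3 changed sign with the scaling. Nrip2, a target in vascular smooth muscle, had -0.31 and Hes7 had 0.33. The list's median was 0.01 (camera adjusted p = 0.997). The 30 Notch receptors, ligands and pathway components had a median of 0.08 (camera adjusted p = 0.159) and none passed; Jag1 had -0.27, Notch2 -0.28, Dll1 -0.28, Jag2 0.35 and the coactivator Maml2 0.33 (0.04 and 0.63).

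Urothelial genes were higher in Rbpj-cKO ureters by a small amount by camera with the preset correlation, and not by fry or with an estimated correlation (adjusted p = 0.792 with an estimated correlation). The 37 genes had a median log2 ratio of 0.21, with 0.20 on the male and 0.28 on the female array; 20 were higher on both arrays and 0 were lower on both. No member passed the limma test, over all genes or adjusted over the list alone. The basal keratin Krt5 had 0.55 and the transcription factor Gata3 0.44, while the ligand Shh had -0.12 (-0.73 and 0.49) and Snx31 -0.09 (-0.60 and 0.42). The 36 proliferation genes had a median of 0.17 (0.10 on the male and 0.31 on the female array), again with 20 higher and 0 lower on both arrays, and among them Top2a had 0.38 and Mki67 0.37. The camera adjusted p was 3.71e-07 for the urothelial and 6.14e-06 for the proliferation list, and 0.792 for both with an estimated correlation.

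The 33 WNT signalling genes had a median of 0.19 (0.31 on the male and 0.04 on the female array), with the ligand Rspo1 at 0.90 and the receptor Lgr5 at 0.82 (1.46 and 0.17) as the highest and Rspo2 at -0.67 (-0.14 and -1.20) and Dkk2 at -0.44 as the lowest. Rspo1 had 2.17 on the male and -0.37 on the female array. Mesothelial markers (12 genes, Rspo1 among them) had a median of 0.24 (0.58 on the male and -0.21 on the female array). Of these, Muc16 had 0.49 (1.18 and -0.21) and Lrrn4 -0.31 (1.01 and -1.63). Kidney epithelial markers (16 genes) had 0.10, with Six2 at 1.17, Cdh16 at 0.75 (0.21 and 1.29) and Cited1 at -0.59, and Six2 rose when adjusted over the list alone. No member of these lists passed over all genes. The camera adjusted p was 0.000401, 0.00121 and 0.0286 in that order, and 0.792 for each with an estimated correlation. The call for kidney markers was lost under 4 other settings.

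Markers of pericytes and vascular mural cells (15 genes) had a median of -0.18 (-0.02 on the male and -0.32 on the female array), with Kcnj8 at -0.68 and Des at -0.64, both of which fell when adjusted over the list alone, and Gja4 at 0.14. Nerve and glial markers (23 genes) had -0.17 (0.13 on the male and -0.25 on the female array). The neurofilament Nefm had -0.63 (-0.05 and -1.20) and the catecholamine enzyme Th -0.59 (0.61 and -1.79). The peripherin gene Prph had 0.36 and Ret 0.34 (0.65 and 0.03). Markers of gonad, adrenal and genital ducts (12 genes) had -0.17, with Fst at -0.52 (-0.18 and -0.86), Sox9 at -0.47 and Star at 0.23. Immediate early genes (22 genes), which respond to handling, had -0.11 (0.10 on the male and -0.30 on the female array). Of these, Egr1 had -0.53, Egr2 -0.42 (-0.14 and -0.69) and Arc 0.10. The camera adjusted p was 0.00175, 0.0200, 0.0251 and 0.0168 in that order, and 0.792 for each with an estimated correlation, and no member passed over all genes.

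The other 12 lists tested did not pass, and no member of these passed over all genes; erythroid and cholesterol genes passed with camera on ranks, and adipocyte markers without a filter on dim probes. Fibroblast and ureteric mesenchyme genes had a median of 0.03, with Foxd1 at -0.82 and Mfap4 falling with it when adjusted over the list alone, Dpt at -1.05 (-0.20 on the male and -1.90 on the female array) and Prrx2 at 0.36 (0.64 and 0.08). Genes of BMP and TGF-beta signalling had 0.07, with Bmp4 at 0.56 and Ltbp2 at -0.63 (-0.13 and -1.14). Hedgehog signalling had 0.01 with Foxl1 at 0.55, Hhip at 0.50 and Gas1 at -0.26. Retinoic acid signalling had 0.08 with Aldh1a3 at 0.59 (1.15 and 0.02) and Crabp1 at -0.44, and extracellular matrix genes had 0.07 with Spp1 at 0.42 (1.41 and -0.56) and Thbs1 at -0.42. Endothelial markers had -0.01 with Esm1 at 0.85 (1.47 and 0.23) and Aplnr at -0.47, immune cell markers -0.04 with S100a9 at 0.69 (0.32 and 1.07) and C1qb at -0.49, and erythroid markers 0.19 with Slc4a1 at 0.43 (-0.63 and 1.49) and Hbb-y at -0.36. Adipocyte markers had 0.01 with Plin4 at -1.02, which fell when adjusted over the list alone, and Pparg at 0.15. Cholesterol biosynthesis had 0.08 with Stard4 at 0.33 and Mvd at -0.39, interferon response 0.03 with Ifit1 at 0.52 and Bst2 at -0.54 (0.20 and -1.28), and hypoxia and glycolysis 0.04 with Gapdh at 0.23 (0.74 and -0.27) and Pfkp at -0.38 (-0.91 and 0.15). The camera adjusted p of these lists, the Notch lists and the transcriptional regulators ranged from 0.126 to 0.997. For 5 lists the median was above 0 while the mean was below 0, namely the smooth muscle regulators, the Notch targets, and the fibroblast, adipocyte and glycolysis genes.

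**Figure D3:**
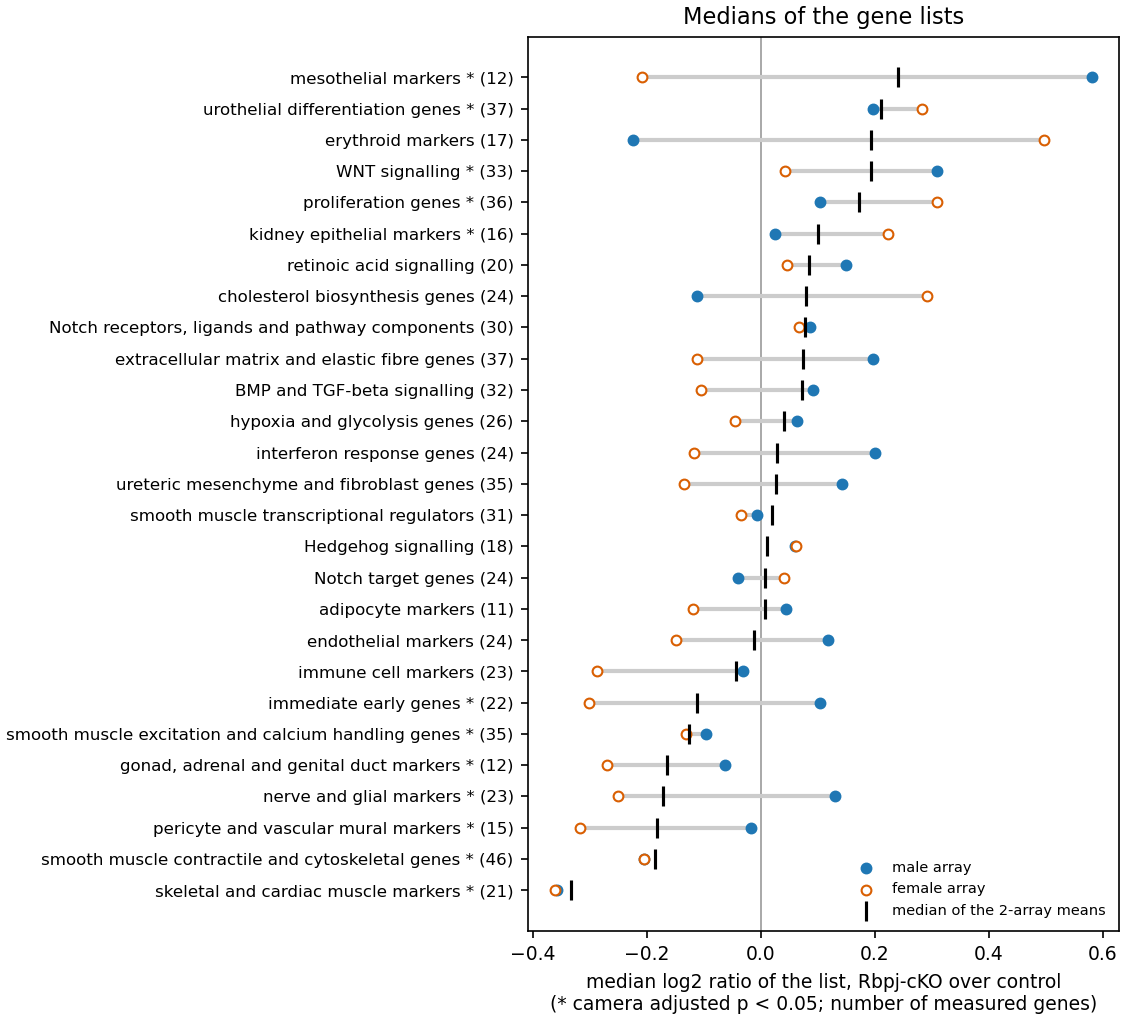
Median log2 ratio of Rbpj-cKO over control (x axis) of each of the 27 gene lists, with the number of measured genes; filled circles are the male array, open circles the female array, ticks the median of the means, and stars mark lists past the camera test with the preset correlation. The contractile list lies at -0.21 on both arrays and the urothelial list at 0.20 and 0.28, while mesothelial markers lie at 0.58 on the male and -0.21 on the female array.

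The male and the female array differed widely. Mesothelial markers had a median of 0.58 on the male and -0.21 on the female array, erythroid markers had -0.23 and 0.50, and nerve and glial markers had 0.13 and -0.25. The catecholamine enzyme Th had 0.61 and -1.79, and the anion exchanger Slc4a1 of red cells had -0.63 and 1.49. Across features, which are not independent replicates, the ratios of both arrays had a Pearson r of -0.18 and a Spearman rho of -0.22. Fitted by limma as a difference that follows dye or sex, 0 features passed at an adjusted p under 0.05 and 2148 had an unadjusted p under 0.05, against 708 for the difference between genotypes and 1049 by chance. Sex goes with dye orientation and with the embryos used, so the difference between the sexes was not tested. The labels of sex were matched by the mean level (log2, male minus female array) of Xist at -4.68 and of the Y-linked genes Eif2s3y at 6.96 and Ddx3y at 5.55.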

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

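All tests of explanations below were chosen after the results were seen. The lists and genes in the next paragraph stand here because the male and the female array went opposite ways. This difference was not tested, and sex goes with dye orientation and with the embryos used.

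The difference of the medians, male minus female on the log2 scale, was 0.789 for mesothelial markers, 0.405 for immediate early genes, 0.382 for nerve and glial markers, 0.318 for interferon response, 0.310 for extracellular matrix, 0.277 for fibroblast and mesenchyme genes, 0.266 for endothelial markers, 0.197 for BMP and TGF-beta signalling, 0.162 for adipocyte markers and 0.109 for hypoxia and glycolysis. It was -0.722 for erythroid markers, -0.404 for cholesterol biosynthesis and -0.0811 for Notch targets. Among single genes the difference was 0.736 for Hes1, 0.398 for Nrarp, -0.586 for Tbx18, -0.390 for Hey2 and -0.182 for Notch3.

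Muscle-list genes past the test (Myh6, Pcp4, Ckm and Myl4) were lower in Rbpj-cKO ureters. A lower share of muscle in the tissue would lower the core smooth muscle markers as far. Each of 62 other genes of the 2 muscle lists was set against the mean of the 5 core markers, with upper bounds that hold over all 62, so that the choice of the lowest genes is allowed for. For these 4 genes alone the upper bound of the difference lay below 0, the closest being Myl4 with -0.177. This argues against such a share as the whole cause of these 4 falls. The other genes lay on both sides of the core mean with upper bounds above 0, such as Tnnt2 (difference -0.724, upper bound 0.15) and Myl1 (0.644 and 1.62). A comparison of the 4 genes alone with the lowest core marker was tried first (-0.975 against -0.782) and did not allow for that choice. Skeletal muscle carried over into control tissue would lower its abundant transcripts alike, but the 21 measured skeletal and cardiac genes had a median of -0.333 (95% bootstrap interval over genes -0.621 to -0.0595), above -0.865, which is 50% of the mean of Myh6, Ckm and Myl4. These 3 were chosen for being low, and the upper bound of their mean over all choices of 3 genes was -1.03. With that choice allowed for, 50% of this bound lies within the interval, so the test cannot exclude carry-over. A subset of 9 fetal skeletal muscle genes was tried first and gave 0.0637. It had been picked after its values were seen and left out lower members such as Tnnc1 (-0.88), so the whole list replaced it. Carry-over thus stays open, both for these 3 falls and for the lower values of other members of the list. For the contractile list as a whole, whose 5 core markers had a mean of -0.271, fewer muscle cells and less RNA per muscle cell cannot be told apart, since no cells were counted. Lower expression of part of the muscle programme without Rbpj, or loss of a subset of muscle cells that expresses these genes, stays open as a hypothesis and was not tested.

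The urothelial list was higher in Rbpj-cKO ureters by camera with the preset correlation, with no member past the limma test, and the call was lost with an estimated correlation (adjusted p = 0.792 with an estimated correlation) and with fry (0.584). A lower muscle share would raise all other cell types alike, but the urothelial mean exceeded that of 168 genes of 9 other non-muscle cell type lists by 0.213 (95% bootstrap interval over genes 0.147 to 0.282). A pool of 105 endothelial, fibroblast, immune and nerve genes was tried first and gave 0.256 (0.178 to 0.332). The urothelial mean was above each of these 4 lists and the adipocyte and gonad lists beyond the bootstrap interval, but not above the mesothelial (mean 0.263 over the 9 genes not in the urothelial list), kidney (0.156) and erythroid (0.113) lists. This argues against a lower muscle share as the whole cause. A shift on 1 array alone is also argued against, since the lower bootstrap bound of the list's median was 0.069 on the male and 0.136 on the female array. The bootstrap draws genes and not embryos, so a difference in dissection between the RNAs, such as more urothelium, stays open beside an effect of genotype, and neither was tested.

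Features changed at least 1.5-fold the same way on both arrays were dense near Tbx18. Within 5 Mb of its probe there were 3 among 56 other features, where 0.359 was expected (exact hypergeometric test, p = 0.00559), and 0.431% of such windows over the genome were as dense. All 3 were RIKEN clone features higher in Rbpj-cKO ureters, with D030062O11Rik (log2 ratio 0.89, chromosome 9, 87626691 to 87626750, mm9) lying 27.2 kb from the Tbx18 probe, and none passed the limma test. Flanking DNA of the strain in which the cre allele was made, or the insertion itself, may account for these 3, and the window was chosen after they were seen. Near Rbpj there were 0 among 25 features with 0.159 expected, too few to exclude such an effect there. Counts over whole chromosomes also varied, with 15 against 7.62 expected on chromosome 1, 13 against 6.6 on chromosome 17 and 2 against 6.73 on chromosome 8. Chromosome 9, which holds Tbx18, had 10 against 7.21.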

How the results depend on the processing

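Among the alternatives, camera without the genes past the limma test and the 2 eBayes options for Rbpj were chosen after the results were seen. Of 26 features past the limma test, 0 passed with median centring without loess, with Agilent's processed signals, with the series value table and without a filter on dim probes, where 226, 837, 817 and 979 had an unadjusted p under 0.05. With the mean of a gene's probes 10 passed and with an intensity trend 41 passed, 10 and 26 of them shared with the 26. The 6 other settings gave 24 to 34. Among them, Aquantile between arrays changes intensities and not ratios, so it returned the main values by construction, here and in the counts below. The 17 named genes past the test kept their direction under each setting that tested them (Mrgprx2 was not tested where all channels had to be above background); the cause of the lost calls was not tested, though without the filter more features (31851) were tested. Features at least 1.5-fold changed the same way numbered 290 with Agilent's processed signals, 260 with the series value table, 208 at 1.4-fold and 29 at 2-fold, against 134, and with a single array (without replicate 2 and without replicate 1) 1147 and 1324 features changed, by construction. Of 12 lists past the camera test, 0 passed with an estimated correlation (lowest adjusted p 0.792) and 0 with fry (0.533). Camera with an estimated correlation also recovered 0 of 9 shifted lists in the simulation, so its loss of calls does not decide. Fry for change in either direction called 2, the contractile and the skeletal and cardiac lists. The 3 muscle lists and the urothelial, proliferation, WNT, mesothelial, pericyte and immediate early lists kept direction and call under the other 11 settings, among them the added one; nerve markers lost the call under 1, gonad markers under 2 and kidney markers under 4, while erythroid, cholesterol and adipocyte genes gained a call under 1 each. The correlation of the arrays across features was -0.352 with median centring (352 features then passed as following dye or sex), -0.0928 with Agilent's processed signals and -0.127 with the series value table, against -0.178. The Rbpj ratio was -1.25 with an adjusted p of 0.0456 when only probes above background in all channels were tested, -1.25 with 0.0126 with an intensity trend, and -1.58 to -0.93 without replicate 1 or 2. Signal over background was lower in red (6.38 and 6.78) than in green (11.2 and 13.3), which limits the ratios of dim probes.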

Other observations

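The genes in this part were picked after their values were seen, from the features changed at least 1.5-fold the same way on both arrays, and none passed the limma test unless stated. Beside Prg4, which passed at 1 of its 2 probes, single genes known from tendon had low values, and no tendon list was set. The tendon transcription factor Scx had -0.88 on the male and -0.90 on the female array, the tendon membrane protein Tnmd had -0.91 and -1.12, and Angptl7 had -0.97 and -0.96. Tendon or cartilage carried over into the control tissue was tested as an explanation, with the bound set before the result of the test was seen but with Scx, Tnmd and Prg4 picked after theirs were. Of 10 other tendon and cartilage genes, the 7 measured (Col2a1, Col9a1, Col11a1, Mkx, Egr1, Fmod and Thbs4) had a median of -0.261 (95% bootstrap interval over genes -0.528 to 0.262), against a bound of -0.546, which is 50% of the mean of Scx, Tnmd and Prg4. The interval clears the bound only narrowly. The bound does not allow for Scx, Tnmd and Prg4 having been picked for their low values. Mkx at -0.67 lies below the bound, while Col2a1 (0.33), Fmod (0.26) and Thbs4 (0.20) lie above 0. The test thus cannot exclude carry-over, which stays open. Genes known from muscle with values below 0 included the caveolin Cav3 (mean log2 ratio -1.04), the fatty acid binding protein Fabp3 (-0.89) and Tnnc1 (-0.88).

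Further single genes, none past the test, are given as values. The ligands Fgf10 (-0.81) and Fgf5 (-0.96) had values below 0 and the BMP antagonist Sostdc1 (0.95) and the WNT antagonist Dkk1 (0.60) above 0, while Bmp4, which was not 1.5-fold higher on both arrays, had 0.56 on average and 0.35 on the female array. The neuropeptide precursor Tac1 had 1.10, and Calca, which encodes calcitonin and its gene-related peptide, had -0.88. Cntn4 (1.05), like Cntn6, encodes a neural adhesion molecule, and its 2 further probes had 0.87 and 0.44.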
